A study of Rattus norvegicus with 17 samples.

How the data were processed

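Skin from 17 explants was hybridised to 1-colour Agilent arrays, 1 array per sample. Per the labels, explants were kept in a preservative, RNA was extracted, and Cy3-labelled cRNA was made from it. The scanner files hold fluorescence intensity on a linear scale, which the authors obtained with Agilent Feature Extraction 10.7.3.1 and its protocol GE1_107_Sep09, per the file headers. Their processed signal is background-subtracted and spatially detrended within each array, per the file headers, and nothing was scaled between arrays. The deposited value table of the series holds log2 values of 14853 probes, and each of its rows has a median of 0. Its columns correlated at 0.981 to 0.999 with the scanner values centred in the same way, with slopes of 0.96 to 1.01 and column medians from -0.037 to 0.041. Its direction and scale were therefore settled from the data, while its scaling step and the rule that chose its probes are not given in the sources used here. It served as an alternative. Each file also holds quality flags per spot, which were written by Feature Extraction per the file headers.

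The main values were log2 of the processed signal minus each array's 75th percentile. Of 62976 spots per array, control spots were left out, spots flagged as non-uniform or population outliers were left out of the mean, and the spots of a probe were averaged, which gave 30367 probes. In 30 pairs of a probe and an array all spots were flagged, and no value was used. A probe counted as well above background on an array when at least 50% of its spots were, and 20709 probes that were so on at least 8 arrays were kept. Of these, 18759 were so on all 17 arrays, and the values of the rest hold some arrays near the floor of the scanner, where differences are less exact. The files give sequence names rather than gene symbols. Those were matched to the symbols of a rat RefSeq table of the assembly GRCr8, used for names only, since the array grid is annotated on another build. A symbol was found for 17998 of the 30367 probes, and 13193 of the kept probes stood for 11166 genes. A gene with several kept probes was read from the one with the highest mean over all arrays. There were 1862 such genes, and for 630 of them the probes differed in the sign of the group difference.

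Exposed and sham arrays were compared with limma 3.58.1 in R 4.3.3, using the moderated test with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. The 31 gene lists, 18 of responses and processes and 13 of cell type markers, were fixed before the data were examined. Of their 408 entries 342 were measured, 18 were too dim and 48 had no named probe. A list score is the mean over its genes of the log2 value minus the gene's mean over all arrays. Scores were compared with a two-sided exact permutation test over all 24310 splits of the arrays into 9 and 8, adjusted over the 31 lists, and 95% intervals came from inverting that test. Named genes were the 12 with the largest change among those past the threshold in each direction, filled by the smallest p where too few passed, as happened for all 24 of them, then the 2 with the smallest p in each list, and 12 stress, inflammation and skin genes chosen in any case, of which Hspa1b, Dnajb1 and Krt10 have no named probe. The values of some genes that this rule names are not reported.

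The arrays lay on 4 slides with 5, 6, 2 and 4 arrays, read from the sample titles. Exposed and sham arrays numbered 3 and 2 on slide 1, 4 and 2 on slide 2, 1 and 1 on slide 3, and 1 and 3 on slide 4. Between slides 0 of 20709 probes differed at an adjusted p under 0.05 in limma, and 1844, or 8.90%, had an unadjusted p under 0.05. Over the list scores slide held from 0.96% of the variance, for cholesterol synthesis, to 48.5%, for immediate early genes. The smallest adjusted permutation p of these shares was 0.472, so no list passed, but an effect of slide is not excluded. Slide entered as a block and each slide was compared alone. Further alternatives were quantile and median scaling, normexp background correction with an offset of 50, both filters on dim probes, array weights, tissue marker scores as covariates, the value table, other set tests, and leaving out each array. The files used here give the median and not the mean pixel signal, so normexp ran on the median signal in place of the planned mean.

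The fit was tested on simulated arrays with the means and residual SDs of 20693 probes, in 20 runs with 200 changed probes each. It recovered 37.2% of probes changed 1.25-fold, 71.3% of those changed 1.5-fold and 90.3% of those changed 2-fold, and 5.03% of its calls were false. Each probe was drawn independently of the others, and the arrays were treated as separate samples. Real probes vary together, and some exposed arrays may share an animal. These rates therefore describe the fit under those settings, and not the recovery or the share of false calls in the real arrays. Over 1000 simulated list scores the permutation test gave p under 0.05 in 5.9% with no shift, in 50.1% with a shift of 1 SD and in 96.6% with a shift of 2 SD.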

Results

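Skin explants of male CD hairless rats, which were 2 to 3 months old at the start, were profiled on 1-colour Agilent rat expression arrays after chronic exposure to millimetre waves. Rats were exposed to 94 GHz for 3 h per day on 3 days per week over 5.5 months, or were sham exposed on the same schedule. The labels put 9 arrays in the exposed group and 8 in the sham group, whereas the design text names 6 exposed and 8 sham animals, so some exposed arrays may share an animal, in which case the p-values are too small. The labels do not tie an array to an animal or a cage, and the p-values measure the spread between these arrays. The 75th percentile of the processed signal ran from 1077 to 1703 over the 17 arrays, and 66.7% to 70.8% of probes lay well above background. That percentage was 68.8 ± 1.13 in exposed skin (SD, n = 9) and 67.7 ± 1.14 in sham skin (SD, n = 8; two-sided exact permutation p = 0.0702). No spot was saturated. The closest pair of arrays differed with an SD of 0.34 log2 units within the exposed group and 0.35 within the sham group, against 0.33 between the groups, so that no pair stood apart as 1 sample measured again. The number of arrays limits the precision of each value.

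The main comparison asked whether chronic 94 GHz exposure altered gene expression in the skin. No gene passed the test: 0 of 20709 probes differed between exposed and sham skin at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and the smallest adjusted p was 0.983. At an unadjusted p under 0.05 there were 943 probes, or 4.55%, of which 123 were higher and 820 lower in exposed skin. Among the 11166 named genes, 416 reached that level, 61 higher and 355 lower. The 95% interval of the difference lay within 1.5-fold either way for 87.4% of probes and within 2-fold for 96.4%. With the median of the kept probes as the scale in place of the 75th percentile, 203 probes were higher and 595 lower at that level, and normexp background correction with the 75th percentile gave 75 and 1024. With slide as a block, 0 probes passed and 705 had an unadjusted p under 0.05. Within slides 1, 2 and 4, which hold too few arrays for a count of adjusted calls to bear on the exposure, the probes at that level were 394 higher and 149 lower, 140 and 676, and 149 and 478; slide 4 has 1 exposed array, and slide 3, with 1 array of each group, gave no test.

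Of the 943 probes at an unadjusted p under 0.05, most were lower in exposed skin, and the lower genes named here each differed by less than 1.5-fold. Usp31, a deubiquitinase gene, had the smallest p of the named genes, with a log2 difference of -0.58 (95% interval -0.86 to -0.31, limma adjusted p = 0.983), and 0 of 9 exposed arrays lay above the sham mean. The difference was -0.59 with slide as a block and -0.32, -0.66, -0.57 and -0.88 on slides 1 to 4, but -0.21 under normexp with quantile scaling. That setting also took Defb51 to -0.16, Atp2b4 to -0.21, Zfp93 to -0.11 and Rims2 to -0.10. Defb51, of the defensin family, was at -0.43 (-0.69 to -0.18). Prostaglandin D2 synthase (Ptgds) was at -0.37, the plasma membrane calcium pump Atp2b4 at -0.36, the serine hydrolase Abhd2 at -0.32, the G protein regulator Rgs2 at -0.28 and the caspase inhibitor Xiap at -0.22. Rims2, Zfp93, Pals1 and Osbpl11 lay between -0.27 and -0.19. On the higher side, Map3k7cl was at 0.64 (0.18 to 1.10) and the carboxylesterase Ces2b at 0.61 (0.16 to 1.07). Prg4, which encodes the lubricant lubricin, was at 0.43, Camkmt at 0.41, Armcx6 at 0.40, Pcdhb4 and Defb29 at 0.39, Ttc12 at 0.30, Enpp4 at 0.24, the focal adhesion gene Fermt2 at 0.20 and glutamine synthetase (Glul) at 0.15. Most of these higher values shrank under normexp with the 75th percentile: Map3k7cl to 0.15, Ces2b to 0.25, Prg4 to 0.10, Ttc12 to 0.20 and Defb29 to 0.0030, while Camkmt, Pcdhb4 and Armcx6 turned to a negative sign. Of the 8 sham arrays, Defb29 and Pcdhb4 were well above background on 2, Armcx6 on 3, and Camkmt and Map3k7cl on 4, so that the sizes of these differences are set in part by background values and are not exact. Enpp4 and Osbpl11 each have another kept probe with the opposite sign. All of these genes missed the adjusted threshold. Of the 92 named genes 65, and of the 31 list scores 29, shrank by over 1.5 times or turned sign under slide as a block, another scaling, normexp background correction or the loss of 1 array, so the values given beside them are examples. The scores of oxidative stress and endothelium, and genes such as Abhd2, Ptgds, Rgs2, Jun and Npas2, did not. That count leaves out the comparisons within single slides. There the oxidative stress score differed by -0.025 on slide 2 and the endothelium score by -0.036 on slide 4, against positive differences on the other slides. On slide 3, with 1 array of each group, Jun was at 0.35, against negative values on the other slides, Abhd2 at -0.048 and Rgs2 at -0.060. Ptgds and Npas2 kept their sign on every slide.

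None of the gene groups that answer to heat and cellular stress passed the test between exposed and sham skin. For the heat shock and cytosolic chaperone list, a readout of heating, the mean score differed by 0.018 log2 units (95% interval -0.065 to 0.10, two-sided exact permutation p = 0.641), with 10 of 13 measured genes higher, 3 lower and 0 past the threshold. With slide as a block it differed by 0.0022, on slides 1 to 4 by -0.064, -0.057, 0.18 and 0.095, and without sham replicate 7 by 0.00044. Among its genes Hsph1, a co-chaperone of the Hsp70 family, was at 0.11 (-0.13 to 0.34) and at 0.031 without sham replicate 5, Hsp90aa1, of whose 2 other probes 1 has the opposite sign, at 0.048 and the small heat shock gene Hspb1 at -0.034, a sign that turned under both quantile settings. Hspa1a, Hspa1b and Dnajb1 of this list have no named probe here, so the score does not cover them. The endoplasmic reticulum stress list differed by -0.0050 (-0.095 to 0.085), although its median gene was at 0.032, with Atf3 at -0.37, Creld2 at 0.13 and the chaperone Hspa5 at 0.065. The sign of that list score turned under quantile and median scaling, with slide as a block and without single arrays, such as sham replicate 8. The oxidative stress and metal list differed by 0.086 (-0.034 to 0.20, exact permutation p = 0.142), with the cystine transporter gene Slc7a11 at 0.60 (-0.13 to 1.32), Nqo1 at 0.27 (0.14 without exposed replicate 5) and Hmox1 at -0.11 (-0.016 without exposed replicate 3). The DNA damage and p53 list differed by -0.011 (-0.065 to 0.045), with Sesn2 at -0.19, Tp53inp1 at -0.15 and the cell cycle inhibitor Cdkn1a at -0.056; its sign turned under median scaling. Hypoxia genes differed by 0.034 (-0.068 to 0.14), or 0.0092 without exposed replicate 1, with adrenomedullin (Adm) at 0.21 and Ldha at 0.10. Of the 10 thermosensitive TRP channels 5 were measured, while Trpm8, Trpa1, Trpm2, Trpm3 and Trpc5 were too dim. The measured channels differed by 0.053 (-0.12 to 0.22), a sign that turned with normexp and the 75th percentile and was not that of the median gene, at -0.0015. Of these channels Trpv4 was at -0.10 and Trpv1, well above background on 6 exposed and 2 sham arrays, at 0.33, a sign that turned with the same setting. The mitochondrial respiratory chain list differed by 0.017 (-0.050 to 0.084), with Cox5a at 0.084 and Uqcrc2 at 0.056, and by -0.00091 without sham replicate 7.

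**Figure D1:**
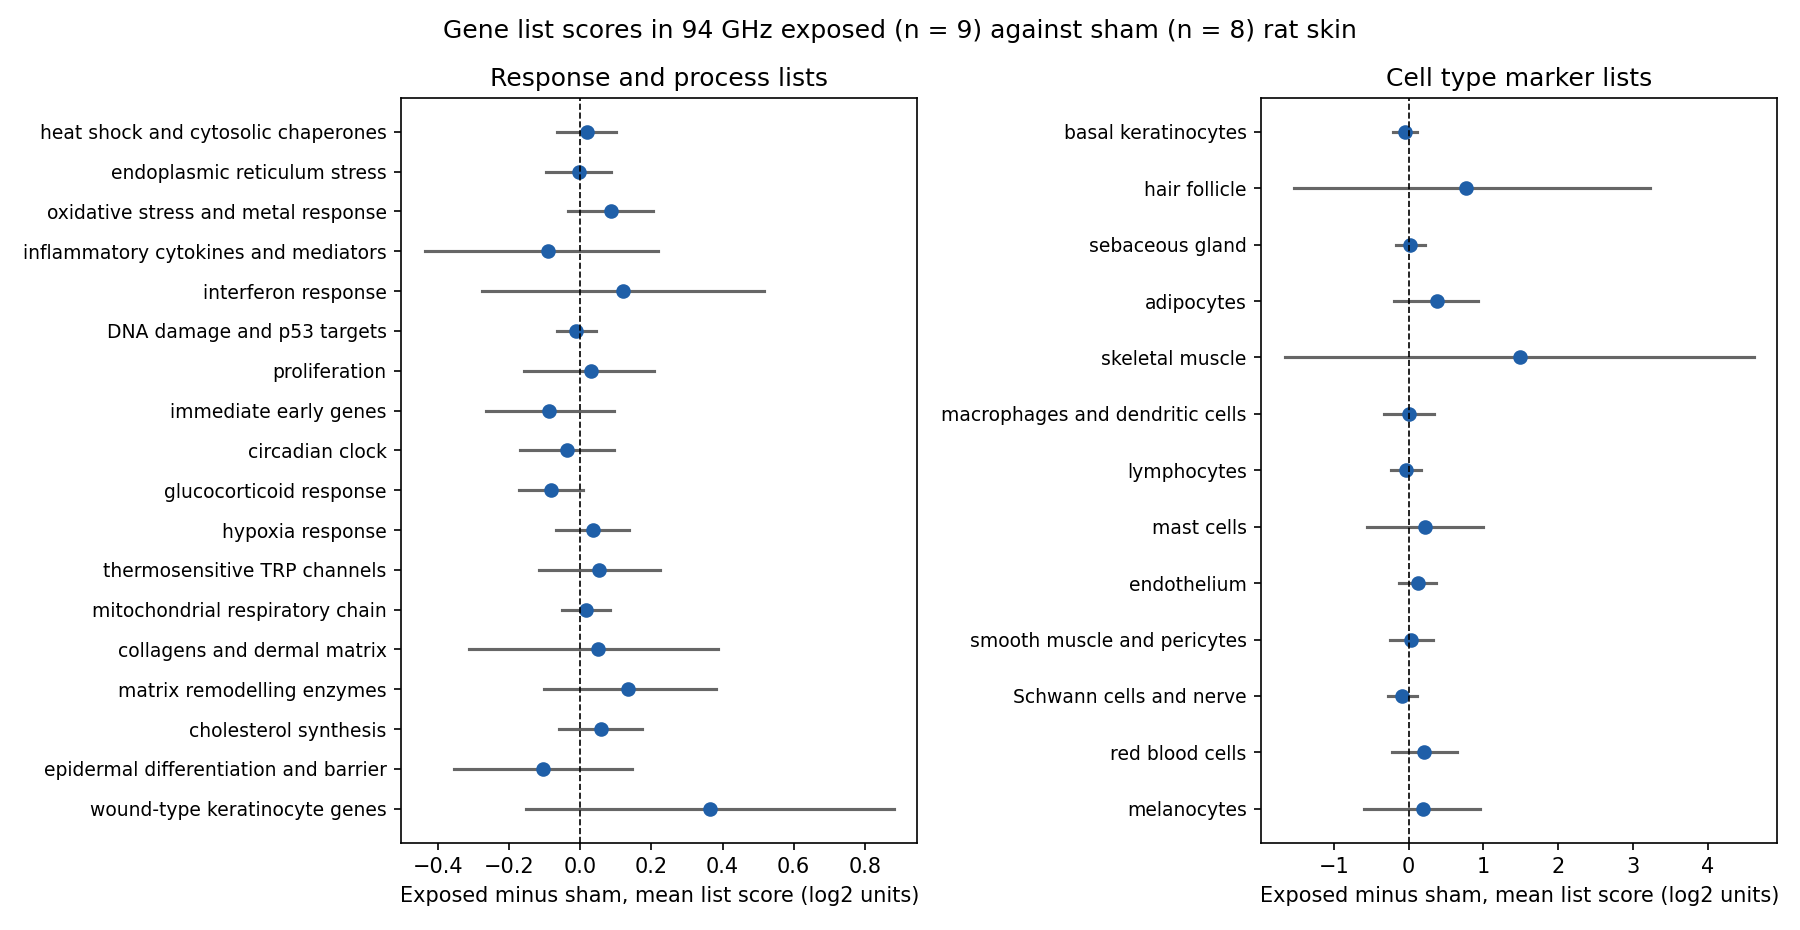
Difference in mean list score between exposed (n = 9) and sham (n = 8) skin in log2 units, for 18 response and process lists (left) and 13 cell type marker lists (right, on a wider axis). Points are the differences and lines the 95% intervals from inverting the exact permutation test; each interval holds 0, and the widest, for skeletal muscle, runs from -1.66 to 4.62.

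Groups tied to inflammation, hormones and growth did not pass the test either. The glucocorticoid response list, genes switched on by corticosteroids, gave the smallest p of the 31 lists, with a difference of -0.083 (95% interval -0.17 to 0.0071, two-sided exact permutation p = 0.0676, adjusted p = 0.880). Of its 11 measured genes 4 were higher and 7 lower, with Zbtb16 at -0.31 (-0.59 to -0.033) and Nfkbia, an inhibitor of NF-kB, at -0.19 (-0.37 to -0.018). With labels permuted within slides that list differed by -0.086 (permutation p = 0.0317, adjusted p = 0.925), and on slides 1 to 4 by -0.059, -0.072, -0.030 and -0.19. Under normexp with quantile scaling it differed by -0.048, and Zbtb16 was at -0.14. The mean score of inflammatory cytokines and mediators differed by -0.091 (-0.44 to 0.22), with Il1b at -0.38 (-0.99 to 0.22) and Nos2, well above background on 5 arrays of each group, at -0.47 (-0.98 to 0.037). That difference was 0.0025 with slide as a block. Without sham replicate 6 it was 0.051, with Il1b at -0.13 and Nos2 at -0.24. Interferon genes differed by 0.12 (-0.28 to 0.52), by 0.26 with slide as a block and by 0.046 without sham replicate 2, with the antiviral gene Rsad2 at 0.83 (-0.15 to 1.80) and Ifit2 at 0.35. Immediate early genes, which answer acute stimuli, differed by -0.087 (-0.27 to 0.093), with Jun at -0.29 (-0.51 to -0.064), Fos at -0.22 (-0.041 without exposed replicate 8) and Ier3 at -0.12. The circadian clock list differed by -0.039 (-0.17 to 0.094), with Npas2 at -0.25 (-0.44 to -0.062) and Ciart at 0.22. That list joins opposite arms of the clock, so a change of phase could cancel in its mean. The arms are compared apart under the other observations. Proliferation genes differed by 0.031 (-0.16 to 0.21), with the replication helicase genes Mcm6 at 0.17 and Mcm2 at 0.077; the score differed by -0.0032 without exposed replicate 6. Cholesterol synthesis differed by 0.059 (-0.061 to 0.17), with 11 of 15 measured genes higher and 4 lower.

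Skin structure genes likewise showed no difference past the threshold. The collagen and dermal matrix list differed by 0.051 (95% interval -0.31 to 0.39), with fibronectin (Fn1) at 0.38 (-0.022 to 0.77), Bgn at 0.15, whose other probe has the opposite sign, and Col1a1 at -0.015, the last of which turned sign under quantile and median scaling. The difference of that list was 0.013 with slide as a block, 0.52, -0.033, -0.82 and -0.16 on slides 1 to 4, and -0.014 without sham replicate 1. Matrix remodelling enzymes differed by 0.13 (-0.10 to 0.38), with the protease inhibitor Timp1 at 0.34 (0.0025 to 0.69) and Mmp9 at 0.52 (-0.85 to 1.90), or 0.047 without sham replicate 5. Of the 15 genes of the epidermal differentiation and barrier list 9 were measured, and Krt10, Lor, Flg, Flg2, Cdsn and Sprr1a had no named probe. The measured genes differed by -0.10 (-0.35 to 0.15), with Krt2 at -0.49 (-1.10 to 0.11) and Casp14 at -0.16. Wound-type keratinocyte genes, raised in injured epidermis, gave one of the wider differences, 0.37 (-0.15 to 0.88, two-sided exact permutation p = 0.147), with 8 of 9 genes higher. The median gene was at 0.10, so the mean rests on a few genes, among them Krt16 at 0.95 (-0.091 to 1.98) and Defb4 at 1.35 (-0.50 to 3.20). Defb4 was at 0.33 under normexp with the 75th percentile and, being well above background on 6 exposed and 2 sham arrays, has no exact size. Over the 31 lists, 0 of the 337 measured genes passed when adjusted over all probes, and 0 passed adjusted over the list alone; 8 had an unadjusted p under 0.05 in limma.

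Marker genes of the tissues in the explants varied far more between arrays than between groups. The skeletal muscle score ranged from -2.99 to 5.42 log2 units over the 17 arrays and was 0.70 ± 3.07 in exposed skin (SD, n = 9) and -0.79 ± 2.94 in sham skin (SD, n = 8; exact permutation p = 0.322). Its difference was 1.49 (95% interval -1.66 to 4.62), with the fast myosin gene Myh1, well above background on 8 exposed and 4 sham arrays, at 3.19 (-1.39 to 7.76) and troponin C (Tnnc2) at 1.98 (-1.53 to 5.49), and was 0.99 with slide as a block and 0.90 without exposed replicate 8. On slides 1 to 4 it was 1.96, 0.49, 3.32 and -1.24. The hair follicle score ranged from -6.63 to 2.64 and differed by 0.77 (-1.54 to 3.23), with the inner root sheath keratin Krt27 at 1.64 (-1.71 to 4.99) and Dsg4 at 0.60. That difference was 0.75 with slide as a block and 0.15, -1.85, 7.24 and 2.01 on slides 1 to 4, and it rests on sham replicate 5, without which it was -0.12. Without that array Krt27 was at 0.0051 and Dsg4 at 0.27. Krt27 was not well above background on sham replicate 5, so its difference and the low end of the hair follicle score are not exact in size. Adipocyte markers differed by 0.38 (-0.19 to 0.92), with all 8 measured genes higher, Fabp4 at 0.52 (-0.077 to 1.12) and Pck1 at 0.82 (-0.24 to 1.88), the last of which turned sign under normexp with the 75th percentile and was well above background on 6 exposed and 3 sham arrays.

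**Figure D2:**
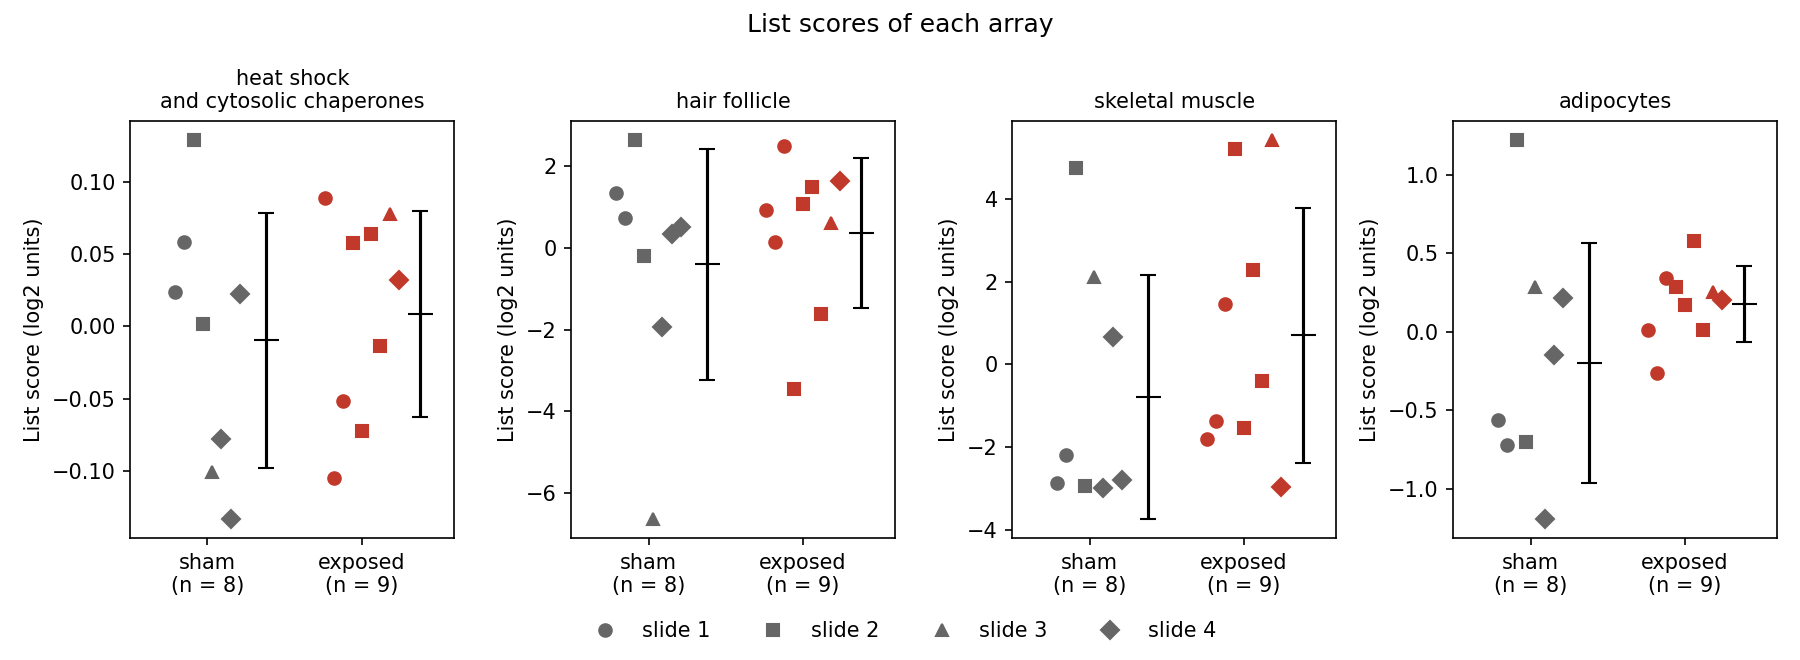
List scores of each array in log2 units, for sham (grey, n = 8) and exposed (red, n = 9) skin, with symbols for the 4 slides and bars for the mean and SD of each group. The hair follicle scores run from -6.63 to 2.64 and the skeletal muscle scores from -2.99 to 5.42 with both groups spread over the range, whereas the heat shock scores stay between -0.13 and 0.13.

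The marker scores of the remaining cell types did not pass the test either. Mast cell markers differed by 0.22 (95% interval -0.56 to 0.99), with the tryptase gene Tpsb2 at 0.36 and Kit at 0.091. With slide as a block that difference was -0.0044 and Tpsb2 was at 0.15. Red blood cell markers differed by 0.21 (-0.23 to 0.64), with Slc4a1, well above background on 8 exposed and 5 sham arrays, at 0.49 and the globin gene Hbb at 0.16. Under normexp with the 75th percentile the score differed by 0.072 and Slc4a1 was at 0.022, and without sham replicate 1 Hbb was at -0.0096. Melanocyte markers differed by 0.19 (-0.59 to 0.96), with Slc45a2 at 0.25 (0.00059 to 0.50) and Mlana at 0.23; the score differed by 0.051 without sham replicate 8, and Slc45a2 was at 0.0087 under normexp with the 75th percentile. Endothelial markers differed by 0.12 (-0.14 to 0.37), with Tie1 at 0.23 and Tek at 0.22. Smooth muscle and pericyte markers differed by 0.035 (-0.26 to 0.33), with Acta2 at 0.15 and Pdgfrb at 0.13, and by -0.048 without sham replicate 1. Sebaceous gland markers differed by 0.020 (-0.17 to 0.21), with Mc5r at 0.21 and Acaca at -0.16, and by -0.042 without sham replicate 1. Macrophage and dendritic cell markers differed by 0.0090 (-0.33 to 0.33), against -0.0040 for the median gene, with Itgam at 0.18 and Cd14 at 0.068; the sign of the score turned under both normexp settings and without single arrays, such as sham replicate 2, and that of Itgam with the 75th percentile. Lymphocyte markers differed by -0.035 (-0.24 to 0.16), with Cd3e at -0.24, and by 0.015 without sham replicate 5. Basal keratinocyte markers differed by -0.047 (-0.21 to 0.12) and by -0.013 with slide as a block, with Krt15 at -0.21 and Krt14 at -0.054, a sign that turned under both quantile settings. Schwann cell and nerve markers differed by -0.085 (-0.28 to 0.11), with Sox10 at -0.20 and Prx at -0.095.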

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

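The test against other genes of the same level was set before its result was seen, and those on the exposure and the slide of the hair follicle score only after it was seen. In 246 checks of a group for 1 array far from the rest, over the list scores and the named genes, 19 stood out, where chance gives about 1 in 20; 4 were list scores and 15 genes, of which 14 are given, and each value below is the log2 difference from the mean of the other arrays of its group.

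Hair follicle genes gave the largest gap: in sham replicate 5 the root sheath keratin Krt27 lay -13.08 from the other sham arrays, a gap whose size is a bound since it was not well above background on that array, and the hair follicle score of that array was -6.63. The exposure as the whole source of the spread in that score is argued against by an SD within groups of 1.02 times the SD over all arrays, and the slide by 0.937 times. A loss of signal left after the scaling and shared by genes of that level is argued against by 240 other genes of the same mean level. Their median had an SD over arrays of 0.0148 times that of the hair follicle score. A loss over a whole array is removed by subtracting its 75th percentile, so these genes cannot show it. Before scaling, the 75th percentile of sham replicate 5 was 1341, within the range of 1077 to 1703 over all arrays. A difference between the rats, the site of the explant or the stage of the hair cycle also stays open, none of which the labels give.

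Sham replicate 6 stood apart in the inflammatory score, by 1.14, in the cytokine gene Il1b, by 2.02, in the myeloid integrin gene Itgam, by 1.41, and in the mast cell tryptase gene Tpsb2, by -1.88. In sham replicate 7 the endothelium score lay 0.67 from the others, the angiopoietin receptor gene Tek 0.83, Ces2b 0.99 and the heat shock gene Hspb1 -0.33. Exposed replicate 4 lay -0.56 from the others in the proliferation score and -3.10 in the erythroid gene Slc4a1, likewise a bound since it was not well above background on that array. Exposed replicate 2 lay 0.54 in the matrix remodelling score and 0.93 in Timp1. Exposed replicate 3 lay 1.44 in Ces2b and 1.08 in the fat cell gene Fabp4. Single genes stood out in exposed replicate 9, with Nfkbia at -0.28, in sham replicate 5, with the melanocyte gene Mlana at 1.77, and in sham replicate 8, with the defensin gene Defb4 at 4.90, a gap whose size is a bound since it was well above background on 1 of the 7 other sham arrays.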

How the results depend on the processing

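The fit with 3 tissue covariates and both fits without a pair of arrays were chosen after seeing the data. In each of the 34 other limma fits, 0 probes had an adjusted p under 0.05, with the smallest adjusted p between 0.233, without sham replicate 2, and 1.00. Leaving out each array in turn gave 0 to 0 probes and 680 to 1354 at an unadjusted p under 0.05. Dropping the 2 arrays of lowest correlation with the rest, sham replicate 5 and exposed replicate 4, gave 0 probes and 1085 at that level. Sham replicates 5 and 6, first left out when they were mistaken for that pair, gave 0 and 926. The 3 covariates gave 0 and 836. Within slide 4 the lone exposed array was assumed to vary like the others. A threshold of unadjusted p under 0.05 with 1.5-fold took 19 probes, 12 higher and 7 lower, by its looser construction. For the list scores, camera with a preset correlation called 10 of 31 lists, all higher in exposed skin relative to other genes: adipocytes, skeletal muscle, endothelium, hair follicle, mast cells, wound-type keratinocytes, cholesterol synthesis, oxidative stress, hypoxia and matrix remodelling. None of these calls held with an estimated correlation (smallest adjusted p = 0.622). The smallest adjusted p was 0.807 in the directional fry test, and it lay between 0.337 and 0.985 over the 31 settings other than the preset one. Leaving out each array in turn gave 0 lists each time. Of 92 named genes 78 and of 31 list scores 17 had the same sign under all settings except the comparisons within single slides. With slide as a block, 4 genes and 11 scores shrank by over 1.5 times or turned sign; under another scaling 41 and 19 did, and without 1 array 37 and 27 did, so that most values depend on these choices or on 1 array. The score of heat shock and cytosolic chaperones, 0.018, was -0.0010 without the 2 arrays of lowest correlation and -0.0085 without sham replicates 5 and 6. No paired analysis was possible because the replicate numbers are only names in accession order. Signal over background limits the dim probes: 1950 of the kept probes were not well above background on at least 1 array.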

Other observations

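The tests on hour of sampling, slide for the pairs of scores, and other splits of the arrays were set before their results were seen, and those on deeper tissue, hair cycle stage, exposure of the clock arms and their relation to hair follicle genes, and the splits under other scalings and within slides only after. The strongest variation in the data separated arrays, not groups. A first principal component with 31.7% of the variance followed the hair follicle score, and the second, with 19.2%, the skeletal muscle score; neither differed by exposure (two-sided exact permutation p = 0.536 and 0.254). Chosen after their values were seen, Krt27, the hair keratin Krt34 and the hair keratin-associated gene Krtap15-1 spanned 14.6, 12.7 and 14.4 log2 units over the arrays, and the muscle genes Myh1, Myh8 and Tnnc2 spanned 13.5, 12.7 and 10.4, with the lowest values of some of them near the scanner's floor.

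Over 100 splits of the arrays into 9 and 8, the real one included, up to 3 probes passed an adjusted p of 0.05 in another split, against 0 in the real one; a count of 0 is reached by any split (100 of 100) and decides nothing about chance. For the count at an unadjusted p under 0.05, 44 of 100 splits gave at least the real 943, so chance cannot be excluded, and the highest other gave 3561, which is several times as many and points to structure among the arrays other than exposure. The balance of those probes stood further out: 87.0% were lower in exposed skin, 37.0 percentage points from an even balance, and 2 of 100 splits lay as far, the highest other at 37.1. Over 5 scalings, those with normexp included, 1 to 4 of 100 splits lay as far, and 3 of 100 when arrays were exchanged within slides only. These shares are under 0.05 without adjustment over the 3 quantities tested on the splits, so chance is not firmly excluded. The balance was 74.6% lower with median scaling and 93.2% under normexp with the 75th percentile, and 27.4% and 82.8% on slides 1 and 2. The 76.2% on slide 4 rests on 1 exposed array and adds little. The median log2 difference over all kept probes was -0.025 in the main fit, -0.0076 with median scaling and -0.039 under normexp with the 75th percentile. Over these settings the balance moved with that small shift of all probes. It did not vanish where the shift was smaller. With quantile scaling the median difference was -0.015 and the balance 81.5% lower, and only the real split of the 100 lay as far. These values do not tell a small shift of all probes from many separate genes falling, so the balance is not evidence for either.

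Skeletal muscle and adipocyte scores varied together over the 17 arrays (r = 0.682, permutation p = 0.00214; rho = 0.738, permutation p = 0.00098; r = 0.765 without the 2 arrays farthest in the muscle score; r = 0.517 over exposed and 0.842 over sham arrays). In a family of 59 relations the adjusted p was 0.0732, so the relation did not pass. Slide as the source is argued against by the slide-centred scores, which still correlated at 0.611 (permutation p = 0.0256). A hypothesis is that some explants may hold deeper tissue, with fat and the thin muscle below the skin. The basal keratinocyte score then falls as the adipocyte score rises, and it did (r = -0.584, permutation p = 0.0127, rho = -0.603, permutation p = 0.0122, -0.614 within slides). Its adjusted p of 0.0254 covers only 2 relations, the other being that between the clock arms given below, and not the 59. Without the 2 arrays farthest in the adipocyte score r was -0.304 (permutation p = 0.271), so that the relation rests on those arrays. The prediction as first written was met, and the demand that it also hold without those arrays was added after the result was seen; the skeletal muscle and basal keratinocyte scores went the same way (r = -0.495, permutation p = 0.0451; rho = -0.593, permutation p = 0.0131; -0.438 within slides) and kept it without the 2 arrays farthest in the muscle score (r = -0.625, permutation p = 0.0128), but with an adjusted p of 0.190 among the 59 relations, so the cause stays open.

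The mean clock score was lower where the hair follicle score was higher, with 10 of its 13 genes at a negative r, Per2, Cry1 and Cry2 at a positive one and 1, Npas2, past adjustment over the 13 (r = -0.673, permutation p = 0.00248; rho = -0.659, permutation p = 0.00547; r = -0.752 over exposed and -0.676 over sham arrays), with an adjusted p of 0.0732 among the 59 relations, so that it did not pass. Without the 2 arrays farthest in the hair follicle score r was -0.492 (permutation p = 0.0619), so the relation rests on them in part. Slide is argued against by r = -0.594 of the slide-centred scores (permutation p = 0.0140). The hour of sampling may still play a part: opposite arms of the clock, with Bmal1, Npas2 and Clock in one and Dbp, Nr1d1, Nr1d2, Per3 and Ciart in the other, would then oppose each other, but their r was 0.317 (rho = 0.331, permutation p = 0.216 and 0.193; 0.141 without the 2 farthest; 0.198 within slides), which does not decide it. The stage of the hair cycle is a candidate explanation, since proliferation genes were higher where the hair follicle score was higher (r = 0.630, permutation p = 0.0125, rho = 0.794, permutation p = 0.00040, 0.575 without the 2 farthest, 0.676 within slides), although its adjusted p of 0.0912 did not pass. That relation cannot tell the stage from the site of the explant or a difference between the rats, so the cause stays open. The oxidative stress and metal score also rose with the hair follicle score (r = 0.645, permutation p = 0.00377, rho = 0.691, permutation p = 0.00321, 0.494 without the 2 farthest, 0.669 within slides). With an adjusted p of 0.0741 among the 59 relations it did not pass.

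The arm with Bmal1, Npas2 and Clock was lower in exposed skin by -0.15 log2 units (-0.072 ± 0.078 against 0.081 ± 0.10, SD, n = 9 and 8; two-sided exact permutation p = 0.0035), in 9 of 9 exposed arrays against the sham mean. This comparison was made after the values of its genes had been seen, and it failed correction, with an adjusted exact permutation p of 0.115 over 33 tests, with the 31 lists and the other arm, which differed by 0.00011 (exact p = 0.999). The exact permutation p lay between 0.0035 and 0.010 over the scalings, those with normexp included, and between 0.0014 and 0.0073 with 1 array left out, and was 0.0075 with labels permuted within slides. This arm also went with the hair follicle score (r = -0.621, permutation p = 0.00735, adjusted p = 0.00764 over 2 arms; rho = -0.593, permutation p = 0.0132; -0.675 without the 2 arrays farthest in the hair follicle score; -0.548 within slides), which was 0.77 higher in exposed skin, or -0.12 without sham replicate 5. With the hair follicle score regressed out of it, the arm with Bmal1 differed by -0.13 (permutation p = 0.00169, before any correction). Only the arm was regressed on that score, with sham replicate 5 included, and the exposure was not adjusted for it. That value is therefore not a separate test of the exposure and does not strengthen the comparison that failed correction.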
